A study of Danio rerio with 4 samples.

How the data were processed

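RNA was measured in hearts of zebrafish larvae carrying the Tg(vmhc:mCherry-NTR) transgene, in 4 groups with 1 library each. The labels give the condition (uninjured or injured) and the compound (SIS3 or DMSO), and each library was placed in its group from those labels. Total RNA was extracted with Trizol and sequenced on an Illumina HiSeq instrument, per the labels' protocols.

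The values are FPKM (fragment counts divided by transcript length and by sequencing depth), computed by the authors and analysed as deposited. The submitters' processing notes name CASAVA 1.8, HISAT2 2.0.5, HTSeq 0.6.1 and the genome build GRCz10, without the role of each. The program that wrote the tables is not given in the sources used here. Per the file headers, each entry is the FPKM of a transcript event (an alternative first exon, last exon, skipped exon, retained intron or exon end) and not of a whole gene. The design written before the data were examined had assumed gene-level FPKM, so a gene level was built from the events. The deposited tables held 53363 entries for uninjured DMSO, 56660 for uninjured SIS3, 47926 for injured DMSO and 51417 for injured SIS3, of which 345, 346, 306 and 293 were repeats and were used once. Only values above 0 are listed.

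The level of a gene was the larger of its summed first-exon FPKM and its summed last-exon FPKM, since either sum can miss a transcript. The 2 sums lay within 0.1% of each other for 69.8%, 69.5%, 69.6% and 69.5% of the loci that had both, in the same order of libraries. A gene not listed in a library was set to 0 there. Such a 0 can be a failed estimate, because genes that most cells use were sometimes not listed, so for single genes the comparisons give values and not folds against a library in which a gene is at 0. The values are not whole multiples of a read, so read counts could not be recovered, the depth of each library is unknown and no counting interval is given. The tables listed 17437, 18207, 15691 and 16657 genes in the same order.

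Libraries were scaled by the median of ratios to the geometric mean of all 4, with log2 factors of −0.12, −0.03, 0.10 and 0.05. All changes are differences of log2(scaled FPKM + 1), a scale that understates the change of low genes. Genes with a mean of at least 1 FPKM over the 4 libraries were compared, which left 13589 of 20269. A gene was called higher or lower at a change of at least 2-fold. With 1 library per group no test was made and no p-value is given. An additive fit of injury and compound over the 4 libraries, which would take the difference between the injury changes as its error, was not run. The comparisons were injury in DMSO, SIS3 after injury, SIS3 without injury, injury in SIS3, and the difference of the injury change in SIS3 from that in DMSO. As deposited, without scaling, the median gene changed by 0.17 for injury in DMSO, −0.04 for SIS3 after injury, 0.07 for SIS3 without injury and 0.05 for injury in SIS3, and changes are given relative to these shifts.

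Gene lists (39 lists of 1174 symbols) were fixed before the data were examined, and 904 of the symbols were measured. For each list the median log2 change was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list is said to stand apart when its median lay in the outer 2.5% at either end, as a description of these libraries and not a test. Lists with fewer than 5 measured genes are given as single values. Symbols came from the gene names in the reference tables, joined on the 18296 gene IDs in the files. Of these, 17308 had a symbol, and 17071 symbols were used after copies of duplicated genes had been told apart by their neighbours in the RefSeq annotation of assembly GRCz12tu. No coordinates were taken from that assembly. The gene entry that holds vmhc has 2 first exons. The order of neighbouring genes there placed vmhc at the one nearer map4l and myh7l at the other, and the entry itself was left out of the lists.

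Named genes followed a rule fixed beforehand. It takes the 10 highest and 10 lowest genes of each pairwise comparison with at least 5 FPKM in the higher library and a symbol that is not a clone name. It adds up to 4 members of each list with the largest change, the 5 highest and 5 lowest genes of the difference, and 20 genes named whatever their values. Any other gene is said to be chosen after its values were seen. The result for 1 gene named by the rule is not reported here.

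Exon inclusion was the percent of scaled FPKM that included an exon, out of the FPKM including or skipping it, for exons with at least 5 FPKM over both forms in all 4 libraries. A difference of at least 20 percentage points was called. This rule was written after the layout of the files was seen and before any share was computed.

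The steps were tested on simulated data with 50 genes changed at each fold and noise of 0.2 (SD, log2). That noise was the same for every gene, and no simulated gene was missing from a library. The noise of the real libraries is unknown, so the simulated shares give no error rate for the calls made here. For injury in DMSO, over 13513 genes, 30% of the genes changed 2-fold, 98% of those changed 3-fold and 100% of those changed 4-fold or 8-fold were called, with 1 of 13389 unchanged genes called. For SIS3 after injury, over 13515 genes, the shares were 34%, 96%, 100% and 100%, with 2 unchanged genes called. For SIS3 without injury, over 13519 genes, they were 36%, 96%, 100% and 100%, with 1 unchanged gene called. For injury in SIS3, over 13513 genes, they were 30%, 94%, 100% and 100%, with 2 unchanged genes called. Of 200 unchanged lists tested for injury in DMSO, 8 stood apart. Of 400 simulated exons, the 100 with a changed inclusion were all called.

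The alternatives planned beforehand were the deposited values without scaling, a trimmed mean of log ratios, pseudocounts of 0.1 and 5 FPKM, no filter, and a filter at a mean of 5 FPKM. First-exon events only, last-exon events only, and only genes listed in all 4 libraries were chosen after seeing the data. Python 3.11, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.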

Results

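Gene expression was measured by RNA sequencing in larval zebrafish hearts at 5 days post fertilization. The Tg(vmhc:mCherry-NTR) line expresses nitroreductase, an enzyme that turns the prodrug metronidazole (MTZ) into a toxin, under a promoter of ventricular cardiomyocytes, so that MTZ ablates these cells. Injury was made with 5 mM MTZ at 72 hours post fertilization, for 4 hours. Larvae then received 2 µM SIS3, an inhibitor of Smad3 phosphorylation, or 0.2% DMSO as vehicle, from 76 to 124 hours. Injured hearts were therefore collected 2 days after treatment. Whether uninjured larvae were exposed to MTZ is not given in the sources used here.

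The 4 groups (uninjured DMSO, uninjured SIS3, injured DMSO and injured SIS3) had 1 library each. There were no replicates, so no difference below has a replicate check or a p-value. The values were FPKM, from which read depth could not be recovered. The libraries listed 17437, 18207, 15691 and 16657 genes in that order. Across genes, the Pearson correlation of log2 levels was 0.965 between the uninjured libraries, 0.954 between the injured ones, and 0.883 to 0.893 between an uninjured and an injured library. Coordinates refer to GRCz10.

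The first comparison asked what ablation of ventricular cardiomyocytes did to the heart in DMSO. Ventricular and contractile transcripts were lower after injury. The order of neighbouring genes places vmhc, which encodes the ventricular myosin heavy chain, at a first exon of the gene listed as ENSDARG00000079782. This exon, called the vmhc first exon below, lies on chromosome 2 at 24614237 to 24614260 on the minus strand. It was at 182 FPKM in the uninjured and 79.9 FPKM in the injured library, a log2 change of −1.18. The second first exon of that entry, at 24633949 to 24633992, was chosen after its values were seen. It lies where the order of neighbouring genes places myh7l, a related myosin gene, and was at 474 and 105 FPKM (−2.17). The natriuretic peptide genes, which cardiomyocytes induce under stress, were higher. On chromosome 8, nppb (ENSDARG00000052958, 48620752 to 48621775) was at 109 FPKM uninjured and 1839 FPKM injured, nppa went from 1071 to 3466 FPKM, and nppal had the largest log2 change of any named gene listed in both libraries (6.62, from 1.09 to 205 FPKM).

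Of 13589 genes compared, 878 were at least 2-fold higher and 1212 at least 2-fold lower after injury. The higher genes made up 42.0% of these calls with scaled values and 57.3% with the deposited values unscaled. Of the lower genes, 305 were not listed in the injured library, and 90 of the higher genes were not listed in the uninjured one.

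Mesenchymal and matrix genes were higher in the injured heart. Of 23 measured factors and markers of epithelial-to-mesenchymal transition (EMT), 11 were at least 2-fold higher and 1 was lower, with a list median of 0.91. The homeobox gene prrx1a (ENSDARG00000033971, chromosome 2, 23509599 to 23517057) went from 4.50 to 61.8 FPKM, and fibronectin 1a (fn1a) from 17.8 to 110.3 FPKM. The EMT transcription factor snai2 (ENSDARG00000040046, chromosome 24, 35501020 to 35507036) went from 14.4 to 59.4 FPKM. The intermediate filament gene vim was the member that was lower, at 36.4 and 5.31 FPKM. The remaining Snail genes were not past 2-fold, with snai1a at 9.49 and 7.73 FPKM and snai1b at 1.63 and 3.22 FPKM. The cadherin of cardiomyocytes, cdh2, was at 88.2 and 143 FPKM, and the epithelial cdh1 at 4.14 and 5.56 FPKM. Among 33 collagen and other matrix genes, 14 were higher and 5 lower (median 0.36). The collagen VI gene col6a1 went from 17.1 to 87.3 FPKM, col5a1 from 13.9 to 61.9 FPKM. Epicardial and fibroblast genes (17 measured, 5 higher and 3 lower, median 0.50) included aldh1a2, which makes retinoic acid, at 31.8 and 191 FPKM, and the secreted chaperone clu at 7.49 and 349 FPKM.

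Immune markers were higher together. Of 21 macrophage markers, 16 were at least 2-fold higher and none was lower, giving the highest list median of this comparison (2.01). They included the lysozyme gene lygl1 (7.38 and 74.6 FPKM), the myeloid transcription factor spi1b (0.446 and 9.15 FPKM) and the complement component c1qb (0.572 and 7.81 FPKM). Of 10 neutrophil markers, 5 were higher (median 1.01), among them lyz at 22.5 and 92.5 FPKM. Inflammatory and wound genes had a median of 0.45 with 9 of 25 higher and 2 lower. The cytokine il11a was at 2.23 and 24.9 FPKM, and the cytokine-signalling inhibitor socs3b at 15.98 and 66.9 FPKM. The interferon list did not stand apart (10 genes, median 0.31).

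Integrated stress and unfolded protein response genes were also higher as a list, with 12 of 28 at least 2-fold higher and none lower (median 0.95). The chaperone BiP, encoded by hspa5, was at 60.4 and 251 FPKM, hsp90b1 at 47.7 and 268 FPKM, and the disulfide isomerase pdia4 at 15.4 and 131 FPKM. Cytosolic heat shock genes did not stand apart (20 genes, median 0.24).

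TGF-β genes moved in both directions. Of 22 genes commonly induced by TGF-β, 2 were higher and 3 lower, and the list median was 0.00. The lysyl hydroxylase gene plod2 (ENSDARG00000011821, chromosome 24, 5205922 to 5282920) was at 21.85 and 81.4 FPKM, whereas the lysyl oxidase gene loxa was at 31.5 and 5.84 FPKM and klf11a at 16.8 and 2.19 FPKM. The inhibitory Smad gene smad7 was at 17.4 and 18.5 FPKM. Among 24 ligands, receptors and Smads (3 higher, 1 lower, median −0.15), the ligand tgfb1b was at 2.41 and 14.2 FPKM and the type I receptor acvr1ba at 25.5 and 99.4 FPKM. The genes of the SIS3 target were at 5.22 and 8.17 FPKM (smad3a) and 6.62 and 4.28 FPKM (smad3b). BMP and Id genes had a median of 0.36, with 2 of 18 higher, among them id3 at 25.8 and 59.0 FPKM.

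Cell cycle lists did not stand apart. No gene of 39 in the G2/M list and none of 35 in the G1/S list was past 2-fold, and the medians were 0.18 and −0.13. The mitotic cyclin ccnb1 was at 20.7 and 36.3 FPKM (log2 change 1.002 with the deposited values unscaled), mki67 at 19.5 and 25.9 FPKM, cdk1 at 63.2 and 71.0 FPKM, and pcna at 308 and 282 FPKM. Genes of p53 and cell cycle arrest went both ways (17 measured, 10 above 0, none at least 2-fold higher and 2 lower, median 0.33), with the lower ones being sesn1 (75.3 and 21.7 FPKM; not listed in either library in last-exon events) and ccng2 (6.15 and 2.01 FPKM; −0.67 with a pseudocount of 5 FPKM) and the inhibitor cdkn1a at 30.8 and 41.7 FPKM. That list did not stand apart, but did on the higher side with a pseudocount of 5 FPKM (0.24) and with the trimmed mean of log ratios (0.33).

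Cardiomyocyte and metabolic genes were lower. Contractile genes had a median of −0.79 (18 measured, 6 lower, 2 higher), with the cardiac actin actc1c at 999.7 and 274 FPKM and the light chain myl7 at 5016 and 2828 FPKM. Calcium handling and ion channel genes had a median of −0.48 (13 measured, 2 lower, 1 higher). Cardiac transcription factors and natriuretic peptides did not stand apart as a list (median −0.25), but the ventricular factors hey2 and irx1a were lower, with log2 changes of −2.13 and −1.90. Notch genes, a list not limited to cardiomyocytes, were lower too (6 of 16, median −0.51), among them notch1a at 10.4 and 1.55 FPKM. Neural and eye genes were lower in the same pair (18 of 20, median −3.27), so the tissue behind the Notch shift is unknown. Glycolysis (11 of 29 lower, 1 higher, median −0.68), nuclear-encoded oxidative phosphorylation (9 of 94, median −0.55), fatty acid oxidation (7 of 27 lower, 1 higher, median −0.43) and ribosomal protein genes (12 of 68, median −0.65) were lower as lists. Examples were the glycolytic gpib (63.9 and 15.0 FPKM), the cytochrome oxidase subunit COX6A1 (445 and 32.3 FPKM) and cpt1b, which moves fatty acids into mitochondria (35.6 and 11.1 FPKM). The range of matched random lists was −0.39 to −0.02 for oxidative phosphorylation and −0.49 to −0.06 for ribosomal protein genes.

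Markers of tissues other than heart were lower in the same comparison. The list medians were −3.35 for exocrine pancreas and intestine (10 of 14 genes lower), −3.27 for neural and eye genes (18 of 20), −1.25 for cartilage and bone (5 of 9), −1.16 for skin (10 of 20), −1.12 for skeletal muscle (8 of 13) and −1.10 for liver (14 of 24 lower, 1 higher). Trypsin (prss1) was at 358 FPKM uninjured and 10.5 FPKM injured. The cone opsins opn1mw2 and OPN1SW were at 103 and 127 FPKM in the uninjured library and were not listed in the injured one. Complement and coagulation genes had a median of −0.69, with 5 of 20 lower and 4 higher. The terminal complement genes c6.2 (50.4 and 324 FPKM) and c7a (40.8 and 269 FPKM) were among the higher ones. Aryl hydrocarbon receptor targets and drug-metabolizing enzymes were lower as a list (5 of 14 lower, 1 higher, median −0.41), though not in 3 of the 9 alternative settings. The complement list did not stand apart with a pseudocount of 5 FPKM (−0.19), the BMP list neither with a filter at a mean of 5 FPKM (0.33) nor in last-exon events only (0.32), and the calcium handling list neither without the expression filter (−0.48) nor in last-exon events only (−0.45).

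**Figure D1:**
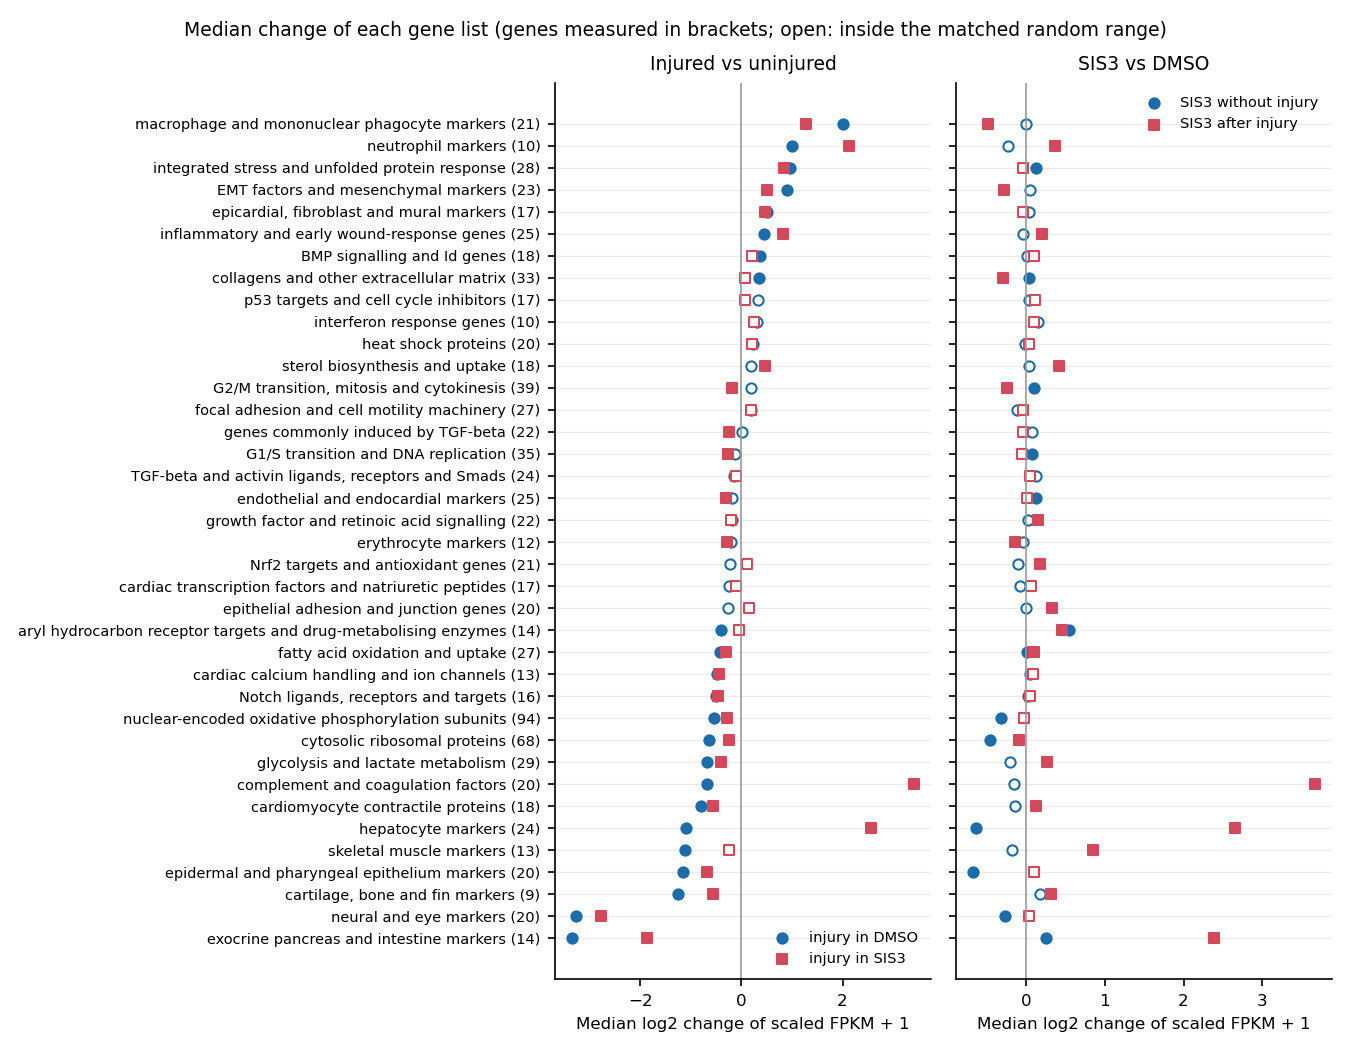
Median log2 change of scaled FPKM + 1 for each gene list (vertical axis, genes measured in brackets), with injury on the left and SIS3 on the right; circles and squares are the 2 independent pairs of libraries, and open symbols lie inside the range of matched random lists. The macrophage median was 2.01 after injury in DMSO and −0.48 for SIS3 after injury, and the liver median was 2.65 for SIS3 after injury.

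The second comparison asked what inhibition of Smad3 phosphorylation did to the injured heart. Genes of EMT, matrix, macrophages and mitosis were lower with SIS3, mostly by less than 2-fold. Snai2 was at 59.4 FPKM in injured DMSO and 38.1 FPKM in injured SIS3, prrx1a at 61.8 and 39.0 FPKM, and the mitotic kinase gene plk1 at 38.3 and 25.5 FPKM. Liver-derived plasma protein genes were far higher, with the fibrinogen gene fgb (ENSDARG00000008969, chromosome 1, 9372135 to 9375385) at 0.997 and 144 FPKM.

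With SIS3 after injury, 434 genes were at least 2-fold higher and 154 at least 2-fold lower. Of the higher genes, 143 were not listed in injured DMSO.

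In the EMT list no gene was past 2-fold, but 16 of 23 were below 0 and the median was −0.27. Besides snai2 (log2 change −0.63) and prrx1a (−0.65), the gelatinase gene mmp2 was at 71.5 and 41.2 FPKM (−0.78) and fn1a at 110.3 and 88.0 FPKM (−0.32), whereas vim was at 5.31 and 5.85 FPKM and cdh2 at 143 and 137 FPKM. Of 33 matrix genes, 26 were below 0 (median −0.29) and 1 was at least 2-fold lower, col6a1 (ENSDARG00000074908, chromosome 11, 33733724 to 33802894; 87.3 and 41.8 FPKM, −1.05), which was past 2-fold neither with a pseudocount of 5 FPKM (−0.98) nor in last-exon events (−0.75). The second collagen VI gene, col6a2, was at 58.3 and 30.6 FPKM. Of 21 macrophage markers, 16 were below 0, with 5 at least 2-fold lower and 2 higher (median −0.48). The transcription factor spi1a was at 11.6 and 3.63 FPKM and c1qa at 6.25 and 1.78 FPKM, neither past 2-fold with a pseudocount of 5 FPKM (−0.95 and −0.73). Among the higher members was the apolipoprotein gene apoc1 (15.9 and 257 FPKM), which liver also expresses.

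In the G2/M list 33 of 39 genes were below 0 and none was past 2-fold (median −0.23). Examples were plk1 (−0.57), the topoisomerase top2a (36.2 and 24.95 FPKM, −0.52) and the checkpoint gene bub1bb (9.19 and 6.14 FPKM, −0.51). Mki67 (ENSDARG00000091150, chromosome 12, 10328774 to 10343439) was at 25.9 and 19.7 FPKM, ccnb1 at 36.3 and 30.3 FPKM, and cdk1 at 71.0 and 57.7 FPKM. The G1/S list did not stand apart (35 genes, median −0.04), with pcna at 282 and 247 FPKM. The cell cycle inhibitor cdkn1a was at 41.7 and 21.8 FPKM (−0.90). Its list, p53 and cell cycle arrest, leaned the other way without standing apart (12 of 17 above 0, 1 at least 2-fold higher, none lower, median 0.12). These 4 lists (EMT, matrix, macrophage and G2/M) stood apart on the lower side under every one of the 9 alternative settings. In the same pair of libraries the liver median was 2.65 and that of pancreas and intestine genes 2.39.

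Genes commonly induced by TGF-β did not stand apart with SIS3 after injury (22 genes, none past 2-fold, median −0.04), nor did the ligands, receptors and Smads (24 genes, median 0.05). The early target smad7 (ENSDARG00000016858, chromosome 21, 3270279 to 3301805) was at 18.5 FPKM in DMSO and 13.7 FPKM in SIS3. Loxa was at 5.84 and 11.04 FPKM, smad3a at 8.17 and 7.50 FPKM, and smad3b at 4.28 and 4.63 FPKM. The lists of the unfolded protein response (28 genes, median −0.04), Notch (0.05), endothelium (25 genes, 0.01), epicardium and fibroblasts (17 genes, −0.03), focal adhesion (27 genes, −0.04) and BMP and Id genes (0.10) did not stand apart either, except that the epicardial list did on the lower side without the expression filter and with a filter at a mean of 5 FPKM (−0.17 in both). The first exon placed at vmhc was at 79.9 and 84.3 FPKM (0.08), and the one placed at myh7l at 105 and 186 FPKM (0.82). Contractile genes had a median of 0.13 and stood apart on the higher side, with myom2a of the sarcomeric M-band at 17.7 and 32.6 FPKM. Of 18 measured, 12 were above 0, none was at least 2-fold higher and 1 was at least 2-fold lower. Skeletal muscle genes were higher in the same pair (6 of 13, median 0.85), so the tissue behind the contractile shift is unknown. Glycolysis genes were also higher as a list (22 of 29 above 0, median 0.27), with tpi1b at 74.7 and 118 FPKM. Inflammatory genes had a median of 0.21, which was −0.028 with a filter at a mean of 5 FPKM, and ribosomal protein genes a median of −0.08 (48 of 68 below 0).

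Liver genes had the largest shift of this comparison among lists with at least 5 measured genes, together with complement and coagulation genes. Of 24 hepatocyte markers, 19 were at least 2-fold higher and none was lower (median 2.65), and of 20 complement and coagulation genes 16 were higher (median 3.67); the fibrinogen genes count in both lists. The protease inhibitor serpina1 was at 5.77 and 349.8 FPKM, angiotensinogen (agt) at 0.284 and 64.2 FPKM, and the complement component c9 at 2.06 and 80.0 FPKM. Pancreas and intestine genes had a median of 2.39 (8 of 14 higher), with chymotrypsinogen ctrb.1 at 5.81 and 66.2 FPKM, and skeletal muscle genes a median of 0.85 (6 of 13 higher). In the same pair, all 20 epithelial adhesion and junction genes were above 0 (4 at least 2-fold higher, median 0.33), among them the tight junction gene cldni (19.9 and 52.3 FPKM) and epcam (6.99 and 17.1 FPKM; 0.88 with a pseudocount of 5 FPKM). Sterol synthesis genes were above 0 in 17 of 18 cases (median 0.42), with msmo1 at 3.77 and 13.96 FPKM. Aryl hydrocarbon receptor targets and drug-metabolizing enzymes had a median of 0.46 (3 of 14 higher), led by cyp1a (ENSDARG00000098315, chromosome 18, 5738730 to 5749620) at 5.07 and 64.1 FPKM. Neutrophil markers were higher (3 of 10, median 0.37), with the gelatinase gene mmp9 at 2.61 and 14.4 FPKM, although that list no longer stood apart in last-exon events only. Smaller shifts that also stood apart were those of cartilage (0.32), antioxidant (0.17), growth factor and retinoic acid (0.16), fatty acid oxidation (0.10) and erythrocyte genes (−0.14), each of which failed to in at least 1 alternative setting.

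**Figure D2:**
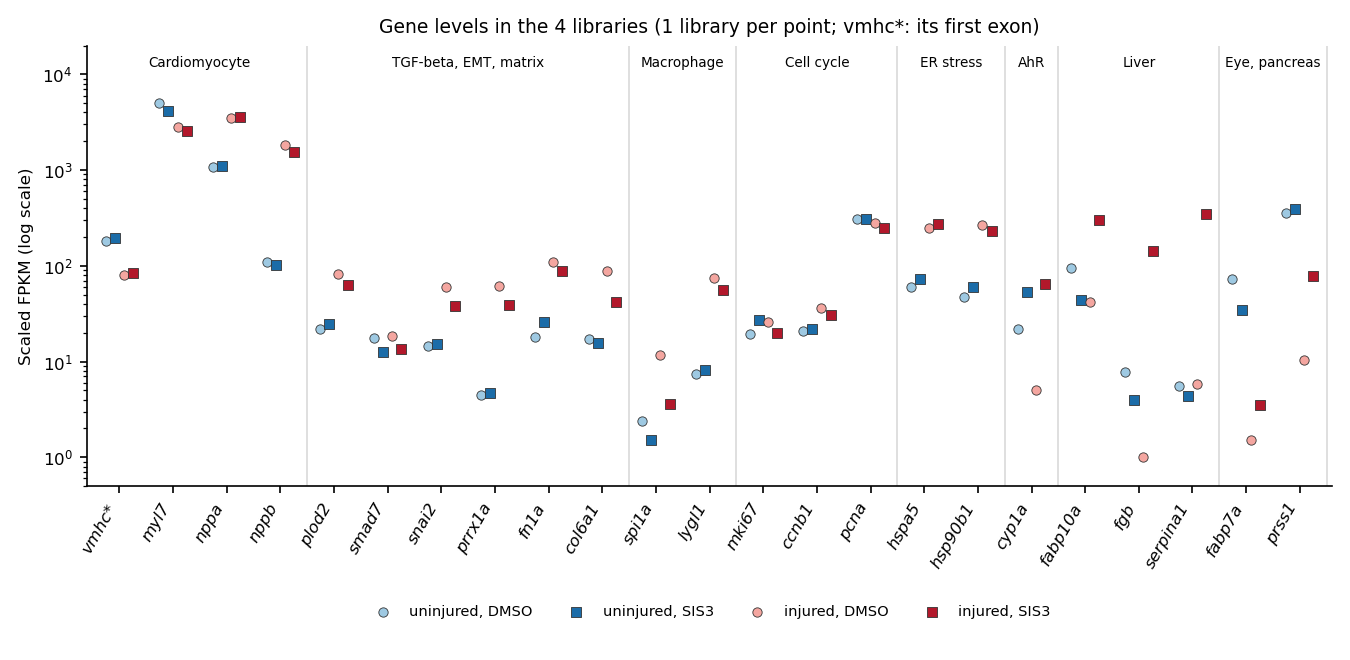
Scaled FPKM on a log axis for genes named in the text, grouped by function along the horizontal axis, with 1 point for each of the 4 libraries. The first exon placed at vmhc by the order of neighbouring genes was at 182 and 195 FPKM in the uninjured and 79.9 and 84.3 FPKM in the injured libraries. The fgb gene was at 7.78, 3.94 and 0.997 FPKM in uninjured DMSO, uninjured SIS3 and injured DMSO and at 144 FPKM in injured SIS3.

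The third comparison set SIS3 against DMSO in hearts without injury. Fewer genes differed, with 241 at least 2-fold higher and 199 lower. These libraries also differed in markers of other tissues, as given below, so the differences are not all assigned to SIS3. The cysteine protease gene ctsl.1 was at 9.75 FPKM in DMSO and 150 FPKM in SIS3, the galectin gene lgals2b at 11.2 and 154 FPKM, and cyp1a at 21.8 and 53.6 FPKM. The carnosine dipeptidase gene cndp1 was at 52.4 and 1.498 FPKM and the adenylate kinase gene ak1 at 173 and 26.6 FPKM. The intestinal bile acid-binding protein gene fabp6 was at 233 FPKM in uninjured SIS3 and not listed in the other 3 libraries.

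TGF-β targets did not stand apart without injury (22 genes, 1 higher, median 0.08), with smad7 at 17.4 and 12.4 FPKM. EMT genes were centred near 0 (median 0.05, 15 of 23 above 0), with snai2 at 14.4 and 15.2 FPKM and prrx1a at 4.50 and 4.73 FPKM. Macrophage markers had a median of 0.00. Both cell cycle lists stood apart on the higher side, by small amounts: the G2/M median was 0.10 (25 of 39 above 0) and the G1/S median 0.08 (25 of 35 above 0). Mki67 was at 19.5 and 26.9 FPKM, and the kinetochore gene cenpf at 3.78 and 6.95 FPKM. Matrix genes had a median of 0.04 with 3 of 33 higher, among them the elastin gene elnb at 85.6 and 200.3 FPKM, and did not stand apart in first-exon events only (0.02).

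Ribosomal protein genes were below 0 in 65 of 68 cases (median −0.45), with rpl10a at 2741 and 964 FPKM, and oxidative phosphorylation genes in 89 of 94 cases (median −0.32), none of which was past 2-fold. The range of matched random lists was −0.32 to −0.19 and −0.29 to −0.17, so other genes of like expression were also below 0. Contractile genes did not stand apart (18 genes, median −0.14) except on the higher side in last-exon events only (−0.05). Matched random lists were below 0 as well, with a range of −0.33 to −0.06 in the main setting. The vmhc first exon was at 182 and 195 FPKM and the one placed at myh7l at 474 and 678 FPKM (0.51). Aryl hydrocarbon receptor targets and drug-metabolizing enzymes were higher (4 of 14, median 0.54), including the intestinal cyp3a65 at 3.41 and 9.11 FPKM (0.75 with a pseudocount of 5 FPKM). Endothelial (0.13), unfolded protein response (0.13) and fatty acid oxidation genes (0.01) also stood apart on the higher side, the endothelial list not in 2 of the 9 alternatives. Other-tissue markers differed between these libraries as well: the medians were −0.67 for skin (6 of 20 lower, 1 higher), −0.64 for liver (2 of 24 lower), −0.27 for neural and eye genes (7 of 20 higher, 2 lower) and 0.26 for pancreas and intestine (14 of 14 above 0). Complement and coagulation genes were below 0 in 19 of 20 cases (median −0.15) and did not stand apart, but came to on the lower side in 7 of the 9 alternative settings. The keratin gene krt5 was at 204 and 85.0 FPKM, the liver fatty acid-binding protein gene fabp10a at 95.3 and 43.6 FPKM, and the lens crystallin gene crygm2d2 at 16.1 and 58.2 FPKM.

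The fourth comparison, injury in SIS3, used a pair of libraries independent of the DMSO pair and showed whether the injury response was seen again. Stress, EMT and immune genes were again higher: nppb was at 101 FPKM uninjured and 1548 FPKM injured, prrx1a at 4.73 and 39.0 FPKM, and hsp90b1 at 59.7 and 229.9 FPKM. The vmhc first exon was lower, at 195 and 84.3 FPKM (log2 change −1.20), and so was the one placed at myh7l, at 678 and 186 FPKM (−1.86). In all, 866 genes were at least 2-fold higher and 920 lower, so that the higher genes made up 48.5% of these calls with scaled values, and 54.4% with the deposited values unscaled.

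Of these, 464 were higher in both pairs, where independent lists of these sizes would share 56.0, and 600 were lower in both, where 82.1 would be shared. Another 60 genes were past 2-fold in opposite directions, where 136.7 would be. Across genes, which are not independent replicates, the injury changes had a Pearson correlation of 0.64 and a Spearman correlation of 0.65. For the SIS3 changes with and without injury, which also share no library, these were 0.04 and 0.05. Here 30 genes were higher in both (7.70 for independent lists), 14 lower in both (2.26) and 35 opposite (9.09), so that opposite calls exceeded independent lists as well. The genes higher in both included cyp1a and lgals2b, the latter at 4.93 and 81.8 FPKM after injury.

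Macrophage markers (15 of 21 higher, 1 lower, median 1.28), unfolded protein response genes (10 of 28 higher, 1 lower, 0.85), EMT genes (7 of 23 higher, 1 lower, 0.50) and inflammatory genes (11 of 25 higher, 2 lower, 0.82) stood apart on the higher side, the EMT list not without the expression filter (0.24). Neutrophil markers had a median of 2.12 (7 of 10 higher), with mmp9 at 2.23 and 14.4 FPKM. Matrix genes did not stand apart (12 of 33 higher, 5 lower, median 0.08). The cell cycle lists stood apart on the lower side, with medians of −0.19 for G2/M and −0.26 for G1/S, and so did TGF-β targets (2 of 22 higher, 4 lower, −0.26; not apart in last-exon events only). Contractile (−0.56), calcium handling (−0.44), Notch (−0.47), glycolysis (−0.40), oxidative phosphorylation (−0.29) and endothelial genes (−0.30) were lower, as were neural and eye (18 of 20 lower) and pancreas and intestine genes (12 of 14 lower). All 20 complement and coagulation genes were at least 2-fold higher (median 3.41), and 18 of 24 liver genes were higher (1 lower, median 2.56). Epicardial (0.47) and sterol genes (0.47) also stood apart on the higher side, and skin (−0.67), cartilage (−0.56), fatty acid oxidation (−0.31), erythrocyte (−0.30) and ribosomal protein genes (−0.25) on the lower side. The cartilage and erythrocyte lists did not in 3 alternative settings each, nor the epicardial and ribosomal lists in 1 each. In first-exon events only the endothelial list no longer stood apart (−0.21), and the calcium handling list did not with a filter at a mean of 5 FPKM (−0.05), with a pseudocount of 5 FPKM (−0.21) or in last-exon events only (−0.15).

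**Figure D3:**
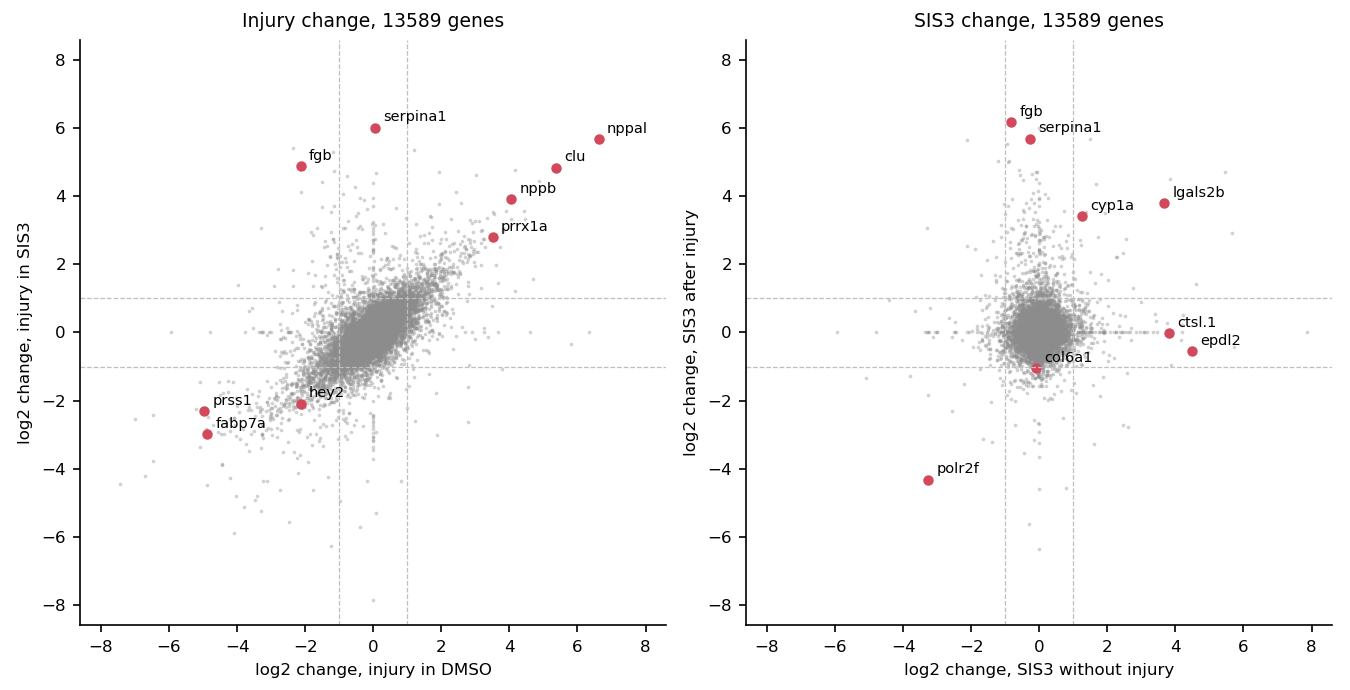
Log2 change per gene (13589 points) in 2 independent pairs of libraries, for injury in DMSO against injury in SIS3 on the left and for SIS3 without against after injury on the right; dashed lines mark 2-fold and red points are named genes. The Pearson correlation across genes was 0.64 for injury and 0.04 for SIS3.

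The difference of the injury change in SIS3 from that in DMSO addressed whether SIS3 altered the injury response, and was at least 2-fold higher for 669 genes and lower for 427. The higher genes made up 61.0% of these with scaled values and 50.9% with the deposited values unscaled. The EMT, matrix, macrophage and G2/M lists were again lower, with medians drawn in part from the same injured libraries: macrophage (median −0.43), G2/M (−0.31, 33 of 39 below 0), EMT (−0.28, 20 of 23 below 0) and matrix (−0.23, 25 of 33 below 0), followed by G1/S (−0.18) and the unfolded protein response (−0.16). The injury change of mki67 was 0.39 in DMSO and −0.43 in SIS3, that of snai2 was 1.98 and 1.27, and that of fn1a was 2.56 and 1.74. Acvr1ba and fn1b differed by −0.01 and 0.00, and nppa by 0.00. TGF-β targets did not stand apart (median −0.08), nor did contractile genes (0.18).

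On the higher side, complement and coagulation (4.09), liver (3.18), pancreas and intestine (1.85), skeletal muscle (0.82), skin (0.75), glycolysis (0.44), epithelial junction (0.33), sterol (0.35), ribosomal protein (0.39), neutrophil (0.38), neural and eye (0.36) and oxidative phosphorylation genes (0.31) stood apart. Of these, the neutrophil list did not in 4 alternative settings, the neural and eye list in 2, and the ribosomal and oxidative phosphorylation lists in 1 each. The range of matched random lists was itself above 0 for ribosomal (0.17 to 0.34) and oxidative phosphorylation genes (0.15 to 0.30). Endothelial (−0.15), epicardial (−0.13) and erythrocyte genes (−0.03) stood apart on the lower side, but not in 6, 1 and 3 of the 9 settings. With a filter at a mean of 5 FPKM the junction (0.20) and sterol (0.34) lists no longer did, nor did the junction list without the expression filter (0.21). The highest genes were agt (7.77), fgb (7.01) and fgg (6.49). Over 760 genes whose injury change averaged over both pairs was at least 2-fold higher, 442 (58.2%) had the smaller change in SIS3, with medians of 1.44 in DMSO and 1.39 in SIS3. Over 951 genes that were lower by the same measure, 624 (65.6%) did, with medians of −1.58 and −1.36.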

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

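Each test of an explanation in this part was chosen only after the result it bears on was seen, while the list medians themselves were planned. The items below are effects of the same contrast that lay on opposite sides in independent pairs of libraries. With 1 library per group, none of these differences was tested.

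The SIS3 change of G2/M genes had a median of 0.10 without injury and −0.23 after injury, and that of matrix genes 0.036 and −0.29. The liver median for SIS3 was −0.64 without injury and 2.65 after injury, and 35 genes were past 2-fold in opposite directions. For injury, the complement and coagulation median was −0.69 in DMSO and 3.41 in SIS3, the liver median was −1.10 and 2.56, and 60 genes were past 2-fold in opposite directions.

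Of 24 liver transcripts, 18 were at least 2-fold higher in the injured SIS3 library than in both injured DMSO and uninjured SIS3. Among the 6 exceptions were apoa1a, at 60.5, 26.9, 8.37 and 28.3 FPKM in uninjured DMSO, uninjured SIS3, injured DMSO and injured SIS3, and tat, at 3.25 and 6.87 FPKM uninjured and 0.93 FPKM in injured SIS3. The liver median for SIS3 without injury was −0.64, so the uninjured pair showed no rise of liver genes with SIS3. This does not exclude SIS3 raising liver genes with or without injury, since the amount of liver tissue in each uninjured library is unknown. Liver tissue in the injured SIS3 library and a response of liver genes to SIS3 that appears only after injury cannot be told apart. That 19 of 24 hepatocyte markers were at least 2-fold higher with SIS3 after injury is the pattern itself and decides nothing between them.

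Transcripts of other organs were higher in the uninjured libraries. Detection of fewer transcripts after injury was excluded as the whole cause, because only 0.678% of 4720 genes at 10 FPKM or more in uninjured DMSO were not listed in injured DMSO, whereas 7 of 10 neural and eye genes (70%) were not. Tissue other than heart in the uninjured libraries and a loss of such transcripts through injury itself cannot be told apart. That 5 lists (neural and eye, pancreas and intestine, skin, cartilage, skeletal muscle) had medians below 0 after injury in both arms is the pattern itself, and the liver list, at −1.10 in DMSO and 2.56 in SIS3, did not share it. Among the most abundant, prss1 was at 358 and 396 FPKM in the uninjured and 10.5 and 78.5 FPKM in the injured libraries.

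EMT, matrix, macrophage and G2/M medians were lower with SIS3 after injury, beside the higher liver transcripts. Dilution of heart RNA by liver RNA would lower all heart lists alike. Of 4 cardiomyocyte and endothelial lists, 0 stood apart on the lower side. Scaling and matched random lists can hide a fall shared by most genes, so that count alone cannot decide. The medians did not move alike, however. They were 0.13 (contractile), 0.09 (calcium handling), 0.06 (cardiac transcription factors) and 0.01 (endothelial). Those of EMT, matrix, macrophage and G2/M genes were −0.27, −0.29, −0.48 and −0.23. That argues against dilution by liver RNA alone as the whole cause. Skeletal muscle genes were also higher in this pair (median 0.85), so dilution by a mixture of tissues is not excluded. A milder injury in the injured SIS3 library cannot be told apart from an action of SIS3: the sarcomere difference of the injury changes was 0.18, inside the range of random lists (percentile 40.2). The same difference was −0.03 for the vmhc first exon, 0.30 for the first exon placed at myh7l, 0.00 for nppa and −0.13 for nppb, and with 1 library per group the spread of these values is unknown. An effect of Smad3 inhibition on these genes, the difference the design names, stays open with it, and the comparison shares the injured DMSO library with the injury comparison in which the EMT, matrix and macrophage lists were higher.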

How the results depend on the processing

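First-exon events only, last-exon events only and only genes listed in all 4 libraries were chosen after seeing the data, while the other settings were planned. No group has a second library, so none could be left out, and an additive fit over the 4 libraries was not run. The next totals count each result once per alternative setting, for 26 counts and correlations, 190 list medians and 728 named-gene results. Of the counts and correlations 181 stayed within their bounds (1.5 times for a count) and 53 moved. Of the list medians 1605 kept their call, whether apart or not, 33 came to stand apart, 60 ceased to and 2 reversed. Of the named-gene results 6052 kept their call at 2-fold, 73 came past it, 138 ceased to and 20 reversed. Filters leave the value of a single gene as it is. The 728 results with no filter, 590 at a mean of 5 FPKM and 649 over genes listed in all 4 libraries were therefore unchanged by construction. Neither scaling alternative moved a count past 1.5 times. Depth was unknown, so its limit on low genes could not be set. Higher and lower counts are written as pairs. With a pseudocount of 0.1 FPKM they were 768 and 379 for SIS3 after injury, 457 and 381 for SIS3 without injury, and 1080 and 811 for the difference, with 1409 lower for injury in SIS3; the injury correlation was 0.60 and the SIS3 pairs shared 90 and 45. With a pseudocount of 5 FPKM they were 348 and 432 for injury in DMSO, 169 and 46 for SIS3 after injury, 68 and 70 for SIS3 without injury, 395 and 262 for injury in SIS3 and 272 and 102 for the difference; the correlation was 0.67, and 207 and 175 genes were shared for injury and 8 and 5 for SIS3. Both shifts follow from the pseudocount's construction, which widens or narrows the changes of low genes. With no filter, 245 were lower for SIS3 after injury, 399 higher for SIS3 without injury, 1040 and 765 for the difference, and the correlation was 0.59, with more genes compared. At a mean of 5 FPKM, with fewer genes compared, the pairs were 523 and 558, 206 and 61, 88 and 109, 544 and 365, and 333 and 144 in the same order, the correlation 0.68, with 257 shared lower for injury and 15 shared higher for SIS3, and the inflammation median for SIS3 after injury was −0.028. In first-exon events the correlation was 0.58, 55 genes were shared higher for SIS3, and the erythrocyte difference was 0.0062. Reversed there were pvalb2 (−0.027) and tnnt3b (−0.0018) for SIS3 after injury, tnnt3b (−0.0036) and acana (0.052) and sult2st3 (−1.41) for injury in SIS3, tnnc1a (−6.89) and col12a1b (−0.28) for SIS3 without injury, tek (0.40) and acana (0.083) for injury in DMSO, and cyt1l (0.62) for the difference. In last-exon events the correlation was 0.59 and 23 genes were shared lower for SIS3. Reversed there were bmp6 (0.57) and rpl36 (6.77) for SIS3 after injury, cmlc1 (3.61), wnk1b (0.19), cryba2b (−0.048) and zyx (−2.04) for SIS3 without injury, zyx (−1.76) for injury in DMSO, and rpl36 (6.77), sesn1 (1.25) and prdx1 (−0.55) for injury in SIS3. Over genes listed in all 4 libraries, 274 and 127 were higher for SIS3 after and without injury, the correlation was 0.67, 382 were shared lower for injury, and 8 and 9 were shared for SIS3. Of these 20 reversals, 7 are against a library at 0 in that setting (cyt1l, tnnc1a, bmp6, rpl36 in both comparisons, cmlc1 and sesn1), so their sizes are not folds between measured levels. For the exon settings the cause was not tested.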

Other observations

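The tests of explanations in this part were chosen only after the values were seen. The exon inclusion rule was written after the layout of the files was known and before any share was computed.

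The inclusion of some exons differed between injured and uninjured libraries. Neural and eye markers were lower and macrophage markers higher after injury in both pairs. A different mix of tissues and a change of exon use within heart cells can therefore not be told apart. Of 1234 exons in 955 genes, 84 were included more and 95 less by at least 20 percentage points for injury in DMSO, and 75 and 86 for injury in SIS3. The direction was shared for 21 exons included more (5.11 for independent lists) and 23 included less (6.62), and opposite for 14 (11.6), and the Pearson correlation across exons was 0.19. An exon of the adhesion gene cd99l2 (chromosome 7, 25614937 to 25614990) was included in 15.7% and 8.92% of FPKM in the uninjured DMSO and SIS3 libraries and in 95.8% and 97.46% in the injured ones. An exon of the spectrin gene sptan1 (chromosome 21, 13093851 to 13093865) went the other way, at 71.5% and 80.9% uninjured and 15.7% and 14.2% injured, as did one of mylk3, a kinase of cardiac myosin light chain (chromosome 7, 41570738 to 41571634), at 49.2% and 54.9% uninjured and 0% and 18.9% injured. Over both forms, the cd99l2 exon rested on 6.91 to 15.41 FPKM, the sptan1 exon on 31.39 to 58.95 and the mylk3 exon on 7.41 to 25.05. The lowest cd99l2 and mylk3 values are near the floor of 5 FPKM.

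With SIS3, 72 exons were included more and 60 less without injury, and 71 and 56 after injury. Across exons these changes had a correlation of 0.003. In both pairs 12 exons of 10 genes were included more (4.14 exons for independent lists) and 4 less (2.72), but 16 went in opposite directions (6.72), so the counts show no common direction. Exons of tjp1a and tjp1b, which encode tight junction scaffold proteins, were among the shared ones. The tjp1a exon on chromosome 7 (30852087 to 30852299) was included in 82.2% of FPKM in uninjured DMSO, 50.2% in uninjured SIS3, 77.1% in injured DMSO and 46.3% in injured SIS3. The tjp1b exon on chromosome 25 (31816884 to 31816919) was at 15.9%, 42.5%, 13.9% and 41.1% in the same order, resting on 6.56 to 10.72 FPKM over both forms. Of 3 mllt10 exons included more in both, 1 (chromosome 24, 17067154 to 17067177) was at 29.1%, 88.1%, 19.1% and 72.8%. It rested on 6.06 to 9.12 FPKM over both forms, near the floor of 5 FPKM. The remaining mllt10 exons had shares identical to each other (0.24%, 40.9%, 0.41% and 39.8%), so they are not separate observations.

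Among gene lists not described above, growth factor and retinoic acid genes were split after injury in DMSO (4 of 22 higher, 3 lower, median −0.19), with the retinoic acid-induced dhrs3a at 2.98 FPKM uninjured and 16.4 FPKM injured and the FGF-responsive etv5b at 16.7 and 4.6 FPKM. Erythrocyte genes (12 measured, −0.22), Nrf2 and antioxidant genes (21 measured, −0.22), focal adhesion genes (27 measured, 0.18) and epithelial junction genes (20 measured, −0.26) did not stand apart there except that focal adhesion genes did with a filter at a mean of 5 FPKM (0.34) and junction genes in last-exon events only (−0.43), although the simple epithelial keratin krt18a.1 was at 138 and 1004 FPKM. In SIS3 without injury, the 6 lens crystallin genes of the neural and eye list were all above 0 (median 1.40), while 3 of the other 14 members were (median −0.48). The mitochondrial gene MT-ND4, the single measured member of its list, was at 49.2 FPKM in uninjured SIS3 and 6.54 FPKM in injured SIS3 and was not listed in either DMSO library.

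Cyp1a was higher with SIS3 in both pairs, at 21.8 and 53.6 FPKM without injury and at 5.07 and 64.1 FPKM after injury. A hypothesis is activation of the aryl hydrocarbon receptor by SIS3, which may raise the receptor's core targets in both pairs. Of 3 core targets, 2 were above 0 in both: cyp1a past 2-fold, and cyp1b1 short of 2-fold with log2 changes of 0.64 and 0.65, while tiparp was at −0.37 and 0.21. Activation of the aryl hydrocarbon receptor by SIS3 and differing amounts of liver and gut tissue cannot be told apart here after injury, since liver and gut also express cyp1a, and 1 library per group leaves the spread unknown. In the uninjured pair the liver median was −0.64 and 22 of 24 liver genes were below 0. These values argue against more liver tissue with SIS3 as the cause there. Activation of the receptor and gut tissue stay open in that pair.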
